A study of Mus musculus with 9 samples.

How the data were processed

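DNA adenine methyltransferase identification (DamID) was measured in single cells and single embryos of the mouse. In this assay a bacterial adenine methyltransferase (Dam) is fused to a protein of interest, or left unfused, and marks GATC motifs near the places where the protein sits. Methylated fragments are then amplified and counted. The constructs were Dam-LMNB1, which carries lamin B1 and marks contacts with the nuclear lamina; Dam-only, which is not tethered and follows chromatin accessibility; Dam-2E12, which carries an antibody fragment expressed in the cell against the Polycomb mark H3K27me3; and Dam-2E12mut, its mutant that does not bind the mark. Per the labels' protocols, zygotes of superovulated females were injected with the construct, cultured, freed of the zona pellucida and taken apart one by one into wells. The labels give the genotype of all 9 libraries as CBABL6F1. Other crosses and marks named in the protocols are not analysed here.

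The deposited tables give, for each well, DamID counts in bins of 10 kb and of 100 kb, counted after removal of duplicates per the file headers, and a call of contact (0 or 1) in each bin of 100 kb. Reads were aligned with Bowtie2 2.3.3.1 to mm10, per the submitters' processing notes. The rule by which the authors called contacts is not given in the sources used here. In the Dam-2E12 library 23.7% of bins were called in contact while 47.2% lay above the mean count of the cell, whereas in Dam-LMNB1 these were 40.5% and 39.4%. Shares of bins in contact were therefore compared only between Dam-LMNB1 and Dam-only. The deposited annotation of the wells gives the construct, the stage, the embryo, whether the well held 1 cell or a whole embryo, and a quality score per well by the authors called IC, which was used only as a description. All 154 wells are annotated as having passed the authors' own filter, and all were used. Construct and stage of each well in the 3 libraries that mix arms came from this annotation, and each one was a construct that the library's title names.

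Counts per 100-kb bin were summed over the wells of 1 construct and stage in 1 library, which gave 12 library arms in 9 libraries. The library, not the cell, is the replicate behind every p-value of the bin comparisons. The labels do not say whether libraries came from separate matings, so these p-values measure the spread between libraries, which may be technical. edgeR 4.0.16 was used with TMM scaling, filterByExpr and the quasi-likelihood test. All 12 arms entered 1 fit with 5 groups, which left 7 residual degrees of freedom (common biological coefficient of variation 0.215, prior degrees of freedom 25.6). Zygote Dam-LMNB1 and 2-cell Dam-2E12 have 1 library each and were assumed to vary like the other groups. Of 27236 bins, 25569 were tested and 1667 were left out, and a bin held a median of 440 mappable GATC motifs. Benjamini-Hochberg adjusted p-values under 0.05 counted as different. Log2 fold changes are given with their standard errors (SE), and levels as CPM scaled by TMM unless stated. GATC counts without duplicates are still not independent molecules, so intervals and floors cover counting error only.

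Gene positions came from a RefSeq table of GRCm38.p6, the assembly known as mm10. It holds no strand, so a gene was placed in the bin of its midpoint in place of its start site, and genes that share a bin share its value. Genes per bin and per Mb count midpoints, so a bin inside a long gene can count as without a gene. Genes of named regions and of single bins called between stages are those that overlap them. Genes of 15 lists were drawn up before the data were examined, and entries marked as pseudogenes were left out. The lists were Hox genes, developmental regulators, housekeeping genes, 2-cell activated genes, pluripotency genes, oocyte genes, olfactory receptors, vomeronasal receptors, beta-defensins, keratins, long neuronal genes, non-canonical imprinted genes, canonical imprinted genes, ribosomal protein genes and histone genes. The symbols Tbxt, Zscan4a and Zscan4e found no entry (Tbxt was matched under its older symbol T). Lists were tested with camera of limma 3.58.1 on each bin once, with an estimated correlation between bins, and adjusted over the 15 lists; the preset correlation of 0.01 was an alternative. Levels of each list per library were compared by an exact permutation of the library arms, two-sided, a test added after the data were seen. The families of receptors, defensins and 2-cell genes hold near-identical copies, so their counts may be split or lost in mapping and are uncertain. Regions were named by a fixed rule: runs of at least 5 adjacent bins past the threshold, the 3 with the highest and the 3 with the lowest mean log2 fold change, at most 1 per chromosome and direction. Of the items these rules name, 1 region and some genes are not reported here. Of each list, the 2 members with the highest and the 2 with the lowest log2 fold change were named (at most 2 examples for families of many copies), along with a fixed set that included Hoxa9, Sox17, Actb, Nanog and Xist.

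Relations between tracks were Spearman correlations across bins, which are not independent replicates. Their two-sided p-values came from all circular shifts of one track along the genome, 25569 at 100 kb and 2628 at 1 Mb, with a smallest possible p of 3.91e-05 and 0.000381. The 12 correlations of this family were adjusted together. Cells were compared by the Pearson correlation of their counts in 1-Mb bins after each was thinned to 3000 counts, a total set after the depths were known so that every zygote stayed in. Only wells with 1 cell entered, in arms with at least 5 such cells. The test on cells of 1 embryo permuted embryo labels within libraries 100000 times, two-sided, so that the smallest p is 1e-05. Shares of bins in contact were averaged over wells per library and compared by an exact permutation of libraries. Wells were called with Y where Y-chromosome counts exceeded 0.05% of autosomal counts, a limit chosen after the values were seen.

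Total counts per well ran from 3358 to 734297, with a median of 113331. The bin test, camera, the shift test and the embryo test were tried on simulated data. For the bin test 50 bins were changed per size and direction, and all arms were given the same spread. For Dam-LMNB1 against Dam-only, 44% of bins made 1 log2 unit higher and 34% of those made 1 unit lower were called, and all 50 of each at 2 units. For Dam-2E12 against Dam-2E12mut these were 4% and 0% at 1 unit, and 70% and 14% at 2 units. For Dam-2E12mut against Dam-only they were 16% and 8%, then 98% and 44%. For the zygote against the 2-cell stage none of the changed 100-kb bins was called at either size. At most 6 of the bins left alone were called in any of these comparisons. Camera found 10 of 10 shifted lists and 1 of 90 unshifted ones at an unadjusted p under 0.05 in the lamina comparison. Those lists held random bins drawn independently of each other. In the real data camera estimated correlations of 0.277 for housekeeping and 0.281 for ribosomal protein genes. The simulation therefore does not show how often camera would find a shift in such lists. Unrelated simulated tracks passed the shift test in 6.0% of 200 pairs, and the embryo test passed in 2.0% of 100 runs without a shared profile.

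The alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit of only the 2 groups, cells thinned to at most 113331 counts, cells of at least 10000 counts, autosomes, 10-kb bins and leaving out each library arm. Further ones were crossed controls, a partial correlation on Dam-only level and GATC number, and the library as a block. Added after the data were seen were 1-Mb bins for the count tests, the embryo as the replicate with library totals as scale, single-cell wells alone, and the ratio of similarity between cells to that between disjoint parts of 1 cell's counts. R 4.3.3 with the data.table package (version 1.17.8) and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. GC content was not used as a covariate, because no genome sequence was used here.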

Results

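Lamina contacts, H3K27me3 and Dam background were profiled in mouse embryos before implantation. The 154 wells came from 105 embryos in 9 libraries and held 23938234 counts. Dam-LMNB1 at the 2-cell stage had 6 libraries with 97 wells (77 single cells and 20 whole embryos) of 61 embryos, and its library totals ran from 881708 to 7696141 counts. Dam-only at the 2-cell stage had 2 libraries with 28 wells and totals of 2202176 and 2124261 counts. Zygote Dam-LMNB1 had 1 library with 8 cells and 52017 counts, from 3358 to 10179 per cell. Dam-2E12 had 1 library with 6 cells of 3 embryos and 521481 counts. Dam-2E12mut had 1 cell with 200198 counts in the library that also held the zygotes (library 8), and 14 cells of 12 embryos with 589531 counts in library 9. Libraries 5 and 6 held both Dam-LMNB1 and Dam-only cells. The title of the series names an antagonism between H3K27me3 and lamina association, and the comparisons follow from that question.

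Which parts of the 2-cell genome lay at the lamina was asked by setting Dam-LMNB1 against Dam-only. Dam-LMNB1 was higher over gene-poor stretches. The strongest was chromosome 2 from 6300001 to 9800000 (mm10), where 35 adjacent bins rose by a mean of 1.47 on the log2 scale, from 30.3 ± 1.2 CPM per bin in Dam-only (SD, n = 2 libraries) to 84.5 ± 14.1 in Dam-LMNB1 (SD, n = 6). It holds only Usp6nl, a regulator of Rab GTPases, and Celf2, an RNA-binding splicing regulator. Next came chromosome 13 from 4700001 to 6600000 (mean log2 fold change 1.39), with the transcription factor gene Klf6, the mitochondrial protease gene Pitrm1 and the phosphofructokinase gene Pfkp. In both regions all 6 Dam-LMNB1 libraries lay above both Dam-only libraries.

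Dam-LMNB1 was lower over gene-dense stretches. The end of chromosome 11, from 114400001 to 121700000, had a mean log2 fold change of -1.75 over 73 bins and fell from 61.0 ± 8.0 to 18.4 ± 2.4 CPM. Its 194 protein-coding genes include the ribosomal protein gene Rpl38, the Polycomb genes Cbx2 and Cbx8, the fatty acid synthase gene Fasn and the actin gene Actg1. On chromosome 8 the 60 bins from 119200001 to 125200000 had a mean log2 fold change of -1.74, with 110 genes such as the forkhead genes Foxf1 and Foxc2, the interferon regulator Irf8 and the mechanosensitive channel gene Piezo1. The lowest run by mean, on chromosome 12 from 22900001 to 23400000 (-1.80), holds only Gm40862 and had few counts, 2.9 ± 1.0 CPM against 11.7 ± 1.6. All 6 Dam-LMNB1 libraries lay below both Dam-only libraries in these regions.

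Over the genome, edgeR's quasi-likelihood test called 13512 of 25569 bins (14782 at an unadjusted p under 0.05), 6159 higher and 7353 lower in Dam-LMNB1. By midpoint, the higher bins held 2.73 protein-coding genes per Mb and 79.5% of them held no gene midpoint. The lower bins held 18.14 genes per Mb and 20.1% were without a midpoint. Bins not called held 5.22 genes per Mb. Across bins the lamina ratio fell with the number of genes (Spearman rho = -0.505, shift p = 3.91e-05, the smallest possible, adjusted p = 0.000117). The Dam-only level, by which this ratio is divided, itself rose with gene number (rho = 0.466). How much of the fall comes from the control was not tested. Called bins were grouped into 1733 higher runs with a median length of 200 kb and 1145 lower runs with a median of 300 kb; the longest were 3.5 Mb and 11.8 Mb. On chromosome 11 50.4% of bins were lower and 18.0% higher, and on chromosome 6 these were 21.7% and 33.8%. The split depended on scaling: the median over all bins was 0.08 with TMM and -0.26 with DESeq2 size factors, under which 2787 bins were higher and 9002 lower, so that 23.6% of calls were higher in place of 45.6%. Without Dam-only library 5 the count was 9259, 2953 higher and 6306 lower, and without Dam-only library 6 it was 7753, 2354 higher and 5399 lower.

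**Figure D1:**
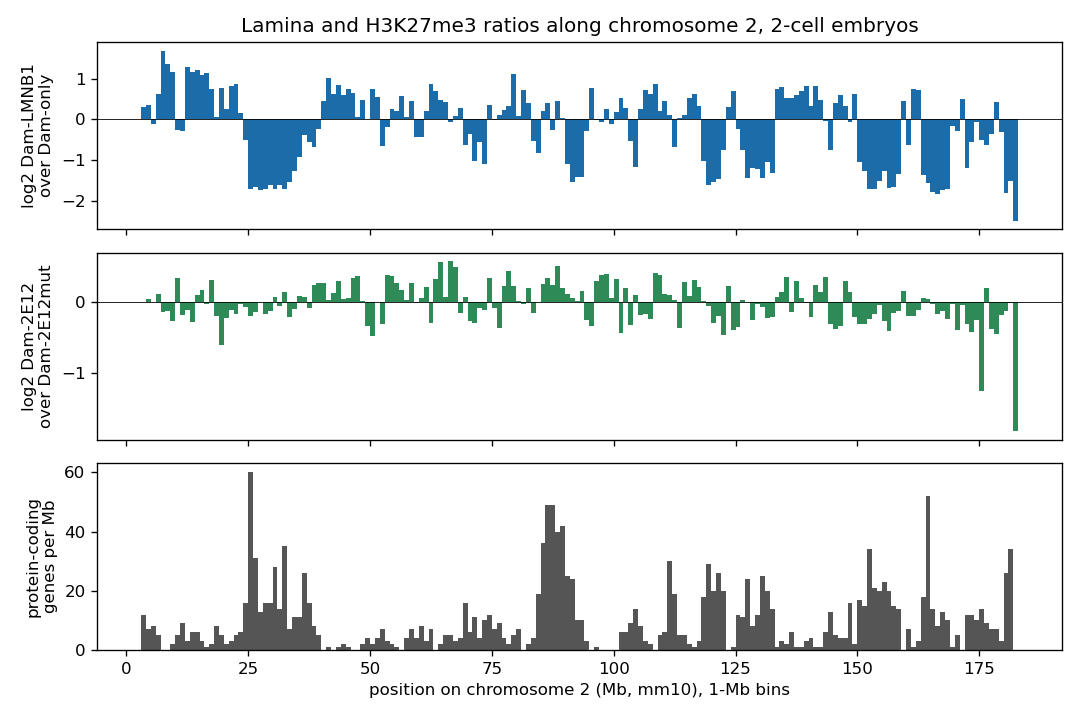
Chromosome 2 in 1-Mb bins (mm10, position in Mb on the horizontal axis), for 2-cell embryos. The bars give log2 Dam-LMNB1 over Dam-only (top), log2 Dam-2E12 over Dam-2E12mut (middle) and protein-coding genes per Mb (bottom). Genes are counted by midpoint. The lamina ratio reaches 1.69 at 7000001, in a bin without a gene midpoint, and is below -1 over much of the gene-rich part between 25 and 35 Mb.

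Genes used in every cell lay in bins where Dam-LMNB1 was lower than Dam-only. All 20 housekeeping genes were lower (20 of 20 bins also when adjusted over the list alone), from Rplp0, a ribosomal stalk protein gene (log2 fold change -1.87, SE 0.235), and the chaperone gene Hsp90ab1 (-1.82) to the purine salvage gene Hprt (-0.90) and the succinate dehydrogenase gene Sdha (-0.62). Actb fell from 102.6 ± 4.9 to 34.7 ± 6.8 CPM and Gapdh from 88.9 ± 18.2 to 26.5 ± 6.3. Of 77 ribosomal protein genes 72 were lower, in 70 of 75 bins (71 adjusted over the list alone), with Rpl23 at -2.09 and Rpl38 at -1.96, while Rps12 (-0.06) and Rps23 (-0.33) did not pass the test. Pluripotency genes were lower in 11 of 12 cases, with 11 adjusted over the list alone. Utf1 stood at -1.96, Fgf4 at -1.60, Zfp42 at -0.82, Nanog at -1.5 and Pou5f1, which encodes OCT4, at -1.51, and Klf4 (-0.39) did not pass. Among the histone genes 50 of 67 were lower, in 9 of 12 bins (9 adjusted over the list alone), led by the linker histone genes H1f8 of the oocyte (-1.86) and H1f0 (-1.84). H2bc1 and H2ac1 share a bin at 0.29 that did not pass (edgeR, adjusted p = 0.361).

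Genes of the early embryo and of Polycomb domains were mostly lower in Dam-LMNB1 than in Dam-only as well. So were protein-coding genes in general, with 13337 in lower bins, 1681 in higher bins and 6298 in bins not called. Counts near that share do not set a list apart. Of 17 genes activated at the 2-cell stage 14 were lower, in 12 of 15 bins (12 adjusted over the list alone), among them Tdpoz4 (-1.77), Tdpoz3 (-1.70), Zscan4c (-1.68) and Zfp352 (-1.43). Duxf3, the gene of the transcription factor DUX, and Usp17ld were not called, at -0.40 and -0.23. Of 39 Hox genes, the patterning genes of the body axis, 30 were lower, in 7 of 9 bins (7 adjusted over the list alone). Hoxb13 had a log2 fold change of -1.67, Hoxb8 of -1.5 and Hoxa9 of -1.38, while the bin of Hoxd3 and Hoxd8 stood at 0.29 and that of Hoxd9 at -0.47, neither past the threshold. Hoxd9 passed only under DESeq2 size factors (edgeR, adjusted p = 0.0103), and so did Pax6 (-0.36, adjusted p = 0.0175 under that scaling). Among 29 developmental regulators 16 were lower and 2 higher (16 and 2 adjusted over the list alone). Pax7, a regulator of muscle and neural crest, stood at -2.40 (SE 0.395), Hand1 at -1.81 and Gata4 at -1.48. Sox17, a regulator of endoderm, rose by 1.42 (SE 0.272), from 37.9 ± 3.5 to 103.1 ± 23.6 CPM, and Dlx5, a homeobox gene of limb and jaw, by 0.74.

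Imprinted, oocyte and epithelial genes varied by list, and their counts are to be read against the same share over all protein-coding genes. Of 6 genes with imprints carried by H3K27me3 in place of DNA methylation, 4 were lower (4 adjusted over the list alone), Slc38a4 at -1.43 and Xist, the RNA of X inactivation, at -1.33, while Sfmbt2 (-0.39) and Smoc1 (-0.52) did not pass. Of 16 imprinted genes with DNA methylation marks 7 were lower and 2 higher (7 and 2 adjusted over the list alone): Nnat and Airn stood at -1.77 and -1.62, and Peg3 and Peg10 at 1.09 and 0.96. Of 15 oocyte genes 9 were lower and 2 higher (9 and 3 adjusted over the list alone). Padi6, needed for cytoplasmic lattices of the egg, stood at -1.85 and Zp3, a protein of the zona pellucida, at -1.75, while the oocyte transcription factor gene Nobox rose by 1.19 and the growth factor gene Bmp15, on the X chromosome, by 1.09. Keratins were lower for 40 of 49 genes, in 11 of 14 bins (12 adjusted over the list alone), with Krt80 at -1.83 and Krt79 at -1.63, and the bin of Krt23 and Krt12 (-0.25) did not pass. Beta-defensins, antimicrobial peptide genes in clusters, had 22 of 42 genes lower and 2 higher, in 7 and 1 of 15 bins (7 and 1 adjusted over the list alone), from Defb28 at -1.73 to Defb41 at 1.02. Over the 15 beta-defensin bins the median was 0.05 and the mean -0.39, and the median was -0.30 under DESeq2 size factors.

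Of 22 long neuronal genes, which code for synaptic and adhesion proteins, 15 were higher (15 adjusted over the list alone), and 8 under DESeq2 size factors. Dlg2, a scaffold protein gene of the synapse, rose by 1.37 (SE 0.280) and Csmd3 had a log2 fold change of 1.19. Csmd1 rose by 0.60 (edgeR, adjusted p = 0.0367, and 0.432 under DESeq2 size factors), and the dystrophin gene Dmd by 1.15 (adjusted p = 0.0093, and 0.0748 under that scaling). The axon guidance genes Robo2 (-0.56) and Robo1 (-0.17) did not pass. Olfactory receptor genes were higher in 57 and lower in 51 of 344 bins (32 and 43 adjusted over the list alone), with Olfr248 at 1.61 and Olfr1371 at -1.85, and under DESeq2 size factors this turned to 16 higher and 82 lower. Vomeronasal receptor genes were higher in 28 and lower in 13 of 177 bins (18 and 11 adjusted over the list alone), with Vmn2r103 at 1.28 and Vmn2r62 at -1.54, and under DESeq2 size factors 4 were higher and 30 lower.

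Levels per library, which come from the counts already tested above, differed between the constructs for 14 of the 15 lists. The direction was not always that of the median bin. Beta-defensins had 35.4 CPM per bin in Dam-LMNB1 and 45.1 in Dam-only, although their median log2 fold change was 0.05. Housekeeping genes had 28.7 ± 4.6 CPM per bin of raw library totals in Dam-LMNB1 (SD, n = 6) and 79.1 ± 5.7 in Dam-only (SD, n = 2), Hox genes had 31.6 ± 3.6 and 57.7 ± 3.9, and long neuronal genes 45.9 ± 3.5 and 23.8 ± 2.4. In 14 lists all 6 Dam-LMNB1 libraries lay on one side of both Dam-only libraries (exact permutation p = 0.0357, the smallest that 28 splits allow, adjusted p = 0.0382). Vomeronasal and long neuronal genes were the 2 higher ones among them, and olfactory receptors, at 38.7 ± 2.1 against 36.2 ± 0.7, did not differ (exact permutation p = 0.179). A list lower than Dam-only was not always low in Dam-LMNB1 itself. Oocyte genes had 40.1 ± 2.5 CPM per bin in Dam-LMNB1, against 56.3 ± 1.8 in Dam-only. Camera, which sets a list against all other bins, called none of the 15 lists in 100-kb bins with an estimated correlation, 6 having an unadjusted p under 0.05. The adjusted p was 0.0767 for Hox, housekeeping, pluripotency, ribosomal protein, vomeronasal and long neuronal genes. It was 0.177 for developmental regulators, keratins and histone genes, 0.146 for 2-cell activated genes, 0.208 and 0.261 for canonical and non-canonical imprinted genes, 0.243 for oocyte genes, 0.463 for olfactory receptors and 0.552 for beta-defensins. With the preset correlation 9 lists were called, Hox, developmental, housekeeping, 2-cell activated, pluripotency, keratin, ribosomal and histone genes lower and long neuronal genes higher. In 10-kb bins with an estimated correlation 7 lists were called: Hox genes (adjusted p = 0.0423) and developmental, housekeeping, 2-cell activated, pluripotency and ribosomal protein genes lower, and long neuronal genes higher (adjusted p = 0.0339 for each of the others).

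**Figure D2:**
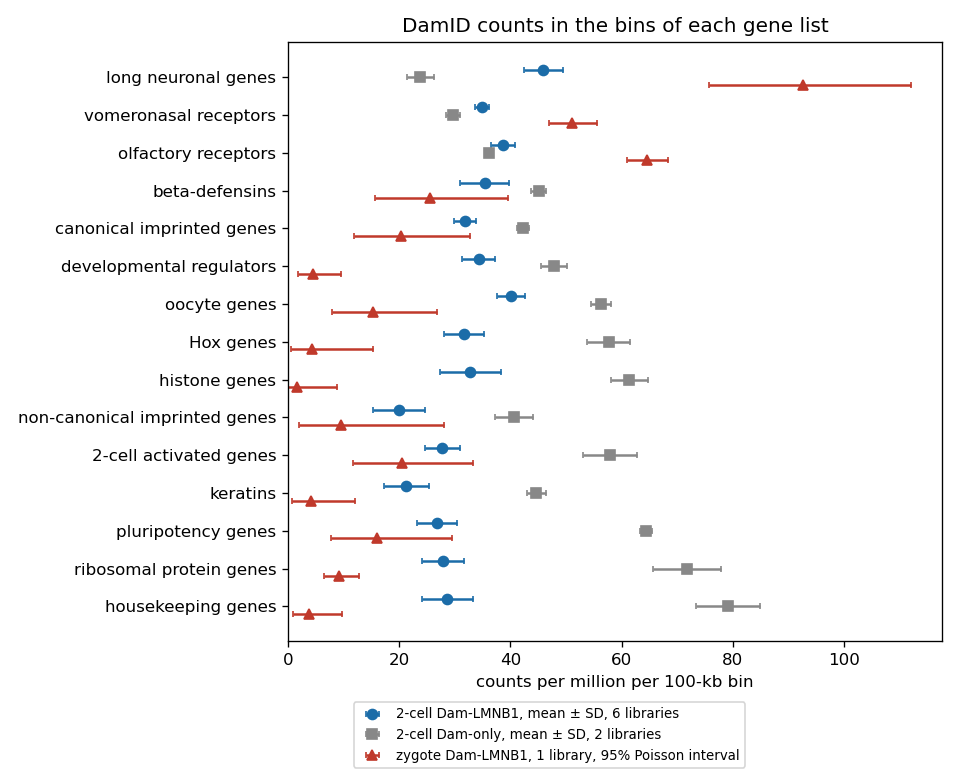
DamID counts in the bins of the 15 gene lists, as CPM per 100-kb bin of raw library totals. Circles and squares are means ± SD over libraries and triangles the zygote library with its 95% Poisson interval. Housekeeping genes stand at 28.7 in 2-cell Dam-LMNB1, 79.1 in Dam-only and 3.8 in the zygote, and long neuronal genes at 45.9, 23.8 and 92.6.

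The X chromosome had the highest median lamina ratio, 0.42, with 480 bins higher and 181 lower. The composition of the embryos differed, however: Y-chromosome counts exceeded 0.05% of autosomal counts, a limit chosen after the values were seen, in 46 of 97 Dam-LMNB1 wells and in 21 of 28 Dam-only wells. In these wells with Y, X counts made up 3.97% ± 0.98 of autosomal counts in Dam-LMNB1 (SD, n = 5 libraries) and 3.84% ± 0.15 in Dam-only (n = 2), exact permutation p = 0.952. In wells without Y these were 8.10% ± 1.37 (n = 6) and 6.72% ± 0.06 (n = 2), exact permutation p = 0.25. The X-linked genes Dmd, Bmp15, Hprt and Xist above were measured over this difference in the number of X chromosomes.

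**Figure D3:**
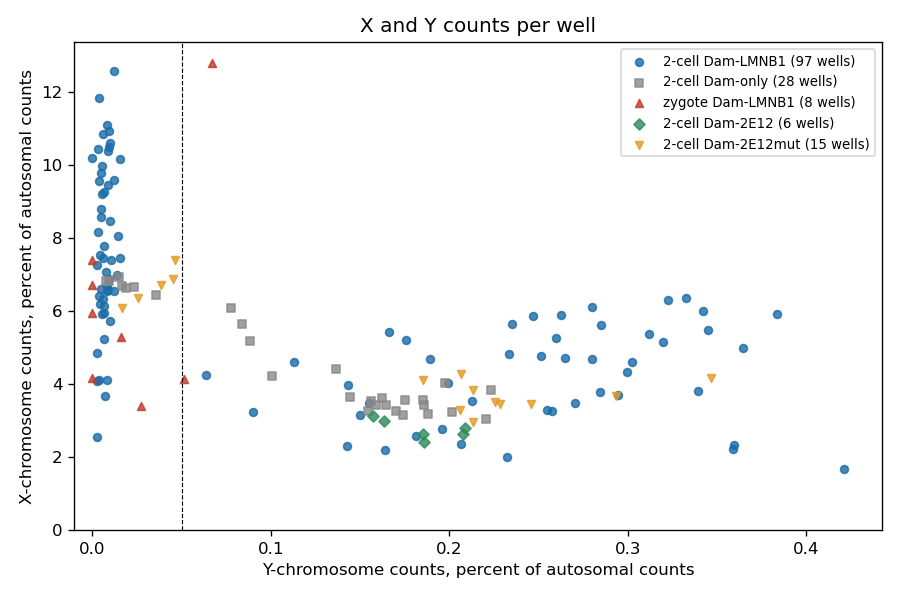
X-chromosome counts against Y-chromosome counts per well, both as percent of autosomal counts, for the 154 wells by construct and stage. The dashed line is the limit of 0.05% above which a well was called with Y; Dam-only wells without Y lie between 6.43% and 6.94%, and Dam-LMNB1 wells without Y between 2.56% and 12.59%.

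Stage was compared by setting Dam-LMNB1 in the zygote against Dam-LMNB1 at the 2-cell stage, without a Dam-only control of the zygote. At 100 kb 10 bins passed the test and all were higher in the zygote. The bin with the largest change lies on chromosome 12 from 67000001 to 67100000 in Mdga2, the gene of a synaptic adhesion protein, with 13 zygote counts (192.1 CPM against 16.6 ± 6.3, log2 fold change 3.52, edgeR adjusted p = 0.0357). On chromosome 13 the bin from 104300001 to 104400000 in Adamts6, a metalloprotease gene, had 19 counts. The other 8 bins held no protein-coding gene; 2 each lay on chromosomes 6 and 16 and 1 each on 3, 9, 12 and 13. The zygote library gave 2.03 counts per tested bin and 10391 bins with 0, so that losses were not detectable at 100 kb; 5796 bins had an unadjusted p under 0.05, and the DESeq2 Wald test called 425 bins, all higher. With edgeR the count fell to 0 with only the 2 groups fitted, with cells of at least 10000 counts, with single-cell wells and in 10-kb bins, and to 1 without 2-cell library 1 or 3.

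In bins of 1 Mb, added after the data were seen, 1237 of 2628 differed, 650 higher and 587 lower in the zygote. With embryos as replicates and library totals as scale these were 487 higher and 956 lower. Higher were gene-poor regions: chromosome 16 from 51000001 to 56000000 rose by a mean of 2.24 on the log2 scale, to 1304.4 CPM per bin (264 counts) from 269.9 ± 33.0 in the 2-cell libraries (SD, n = 6), and holds the adhesion gene Alcam and the ubiquitin ligase gene Cblb. Chromosome 2 from 96000001 to 101000000, which holds the synaptic adhesion gene Lrrc4c alone, stood at 1146.3 against 255.1 ± 51.0. Chromosome 12 from 92000001 to 98000000, with Flrt2, stood at 996.4 against 232.2 ± 23.7. Lower were gene-dense regions. On chromosome 7 from 137000001 to 144000000, with 156 genes such as Utf1, Ebf3 and Cyp2e1, the zygotes had 6 counts (21.2 CPM against 227.2 ± 20.8). On chromosome 5 from 121000001 to 129000000, with 103 genes including the phosphatase gene Ptpn11 and the demethylase gene Kdm2b, they had 8 counts (24.7 against 273.1 ± 20.6). Chromosome 8 from 105000001 to 113000000, with the insulator gene Ctcf, had 26 counts (80.3 against 333.6 ± 31.0). The higher 1-Mb bins held 3.14 genes per Mb and 46.2% of them were also higher in 2-cell Dam-LMNB1 than in Dam-only. The lower ones held 11.78 genes per Mb, with 16.7% higher in 2-cell Dam-LMNB1 than in Dam-only. Bins not called held 9.13 genes per Mb, with 22.1%. At 1 Mb the zygote profile followed the 2-cell Dam-LMNB1 profile (rho = 0.607) and went against gene number when divided by it (rho = -0.491), both at the smallest shift p of 0.000381 (adjusted p = 0.000457).

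By list, the zygote library lay below all 6 2-cell Dam-LMNB1 libraries for 12 lists and above them all for 3. Housekeeping genes had 4 counts, 3.8 CPM per bin (95% Poisson interval 1.0 to 9.8), below all 6 2-cell Dam-LMNB1 libraries at 28.7 ± 4.6. Ribosomal protein genes had 9.2 CPM (6.5 to 12.8) against 27.9 ± 3.8, developmental regulators 4.6 (1.9 to 9.6) against 34.3 ± 2.9, and Hox genes 4.3 (0.5 to 15.4). Genes activated at the 2-cell stage had 16 counts, 20.5 CPM (11.7 to 33.3), an interval that includes the 2-cell mean of 27.8. The same held for pluripotency genes (7.7 to 29.5 against 26.9), beta-defensins (15.7 to 39.6 against 35.4) and non-canonical (2.0 to 28.1 against 20) and canonical imprinted genes (11.9 to 32.7 against 31.9). Long neuronal genes had 92.6 CPM (75.8 to 112.0) against 45.9 ± 3.5, olfactory receptors 64.6 (60.9 to 68.4) against 38.7 ± 2.1 and vomeronasal receptors 51.0 (46.9 to 55.5) against 34.9 ± 1.2. Camera called olfactory and vomeronasal receptors higher in the zygote (adjusted p = 0.0457 and 0.0331 with an estimated correlation), although the medians of their fitted log2 fold changes, pulled down by bins with 0 counts, were -0.09 and -0.35. In 10-kb bins with an estimated correlation neither was called (adjusted p = 0.595 and 0.973). All zygotes came from library 8, so stage and library cannot be told apart.

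Where H3K27me3 lay was asked by setting Dam-2E12 against Dam-2E12mut. No bin passed the test with edgeR (966 at an unadjusted p under 0.05) or with the DESeq2 Wald test (766). At 10000 counts per cell in 1-Mb bins, the Dam-2E12mut cell of library 8 correlated with Dam-2E12 cells at a mean of 0.345, inside their own range across embryos (0.330 to 0.351), and at 0.248 with the other Dam-2E12mut cells. Without it the count stayed at 0, with 1664 bins at an unadjusted p under 0.05. Values of the named genes are therefore descriptions. Hand2, a developmental regulator, stood highest of its list at 1.15 (SE 0.539), Hoxd3 and Hoxd8 at 1.11 (SE 0.643) and Hoxa9 at 0.62 (SE 0.406), whereas Olig2 was at -1.20 and Hoxb4 at -0.63. Sfmbt2, an imprinted Polycomb gene, was at 0.85 (SE 0.651), with 57.4 CPM in Dam-2E12 against 33.5 and 30.9 in the Dam-2E12mut libraries. Among the 6 genes with H3K27me3 imprints 5 were above 0 and Xist was at -0.24, with a list median of 0.34. By raw library totals this list had 56.3 CPM per bin in Dam-2E12. The Dam-2E12mut cell of library 8 had 58.3 and library 9 had 35.9, so the list was higher than library 9 alone. Among the 12 histone bins 11 were below 0, with a median of -0.54. Hox genes had a median of 0.08, developmental regulators -0.02 (0.03 when scaled by library totals), pluripotency genes 0.19, housekeeping genes -0.21, long neuronal genes 0.12 and ribosomal protein genes -0.12. No list passed camera (smallest adjusted p = 0.813 with an estimated correlation, none of 15 with an unadjusted p under 0.05). On the X chromosome the median ratio was -0.66; all 6 Dam-2E12 cells were above the Y limit, as were 10 of the 15 Dam-2E12mut cells. In simulated data this comparison found 70% of bins made 2 log2 units higher and 4% of those made 1 unit higher. Only 50 bins per size and direction among 25517 were changed there. A change of 1 unit in so few bins was thus mostly missed at this depth, and a broad change was not simulated.

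The control constructs, Dam-2E12mut and Dam-only, were compared with each other. No bin passed with edgeR (1125 at an unadjusted p under 0.05) or the DESeq2 Wald test (963), while simulated changes of 2 log2 units upward were found in 98% of bins. Vomeronasal receptors were higher in Dam-2E12mut by camera in 100-kb bins (adjusted p = 0.00499 with an estimated correlation) but not in 10-kb bins (adjusted p = 0.522). Across bins the ratio of Dam-2E12mut to Dam-only fell with gene number (rho = -0.233, shift p = 3.91e-05, adjusted p = 0.000117). The Dam-only level itself went with gene number (rho = 0.466, the same p). In long neuronal genes Dam-2E12mut had 35.0 ± 9.3 CPM per bin (SD, n = 2) against 23.8 ± 2.4 in Dam-only, and in Hox genes 53.9 ± 3.0 against 57.7 ± 3.9. The long neuronal value was 41.5 in the single Dam-2E12mut cell of library 8 and 28.4 in library 9.

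The question in the title, whether H3K27me3 and lamina contacts exclude each other, was put to the ratios of both constructs over their own controls, which share no library arm. Across 25569 bins the lamina ratio and the H3K27me3 ratio did not correlate (Spearman rho = 0.0005, shift p = 0.976). No bin passed the H3K27me3 comparison, which rests on 1 Dam-2E12 library. The lack of correlation could come from little signal in that ratio, so it does not decide the question. By chromosome rho ran from -0.146 on X to 0.149 on chromosome 12. Among the autosomes only chromosomes 6 (-0.052) and 13 (-0.014) had a negative rho. Bins with higher Dam-LMNB1 had a median H3K27me3 ratio of -0.14 and bins with lower Dam-LMNB1 one of -0.13, a difference of -0.01 (p = 0.738, permutation by shifts), and bins not called had 0.02. The sign and the call changed with bin size, the X chromosome and the controls. At 1 Mb the correlation was 0.09 (shift p = 0.00609), on autosomes 0.034 (shift p = 0.022), and with the controls exchanged or with Dam-only level and GATC number held fixed it was -0.082 and -0.084 (shift p = 3.91e-05 for both). Without the Dam-2E12mut cell of library 8 it was 0.0282 (shift p = 0.138), and the difference of medians was 0.038 (p = 0.277, permutation by shifts). By the same permutation, that difference was 0.077 at 1 Mb (p = 0.0019), -0.074 with Dam-only level and GATC number held fixed (p = 0.00086) and -0.036 without Dam-2E12mut library 9 (p = 0.0491). Without a control, the 1-Mb level of 2-cell Dam-LMNB1 went against that of Dam-2E12 (rho = -0.211, shift p = 0.000381) and that of Dam-only (rho = -0.117, the same p).

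The share of bins that the authors called in contact was compared between 2-cell Dam-LMNB1 and Dam-only. Dam-LMNB1 cells had 40.5% ± 2.4 of bins in contact (SD, n = 6 libraries) and Dam-only cells 41.0% ± 1.4 (SD, n = 2), a difference of -0.48 percentage points (exact permutation p = 0.857 over 28 splits). The lowest share in Dam-LMNB1 was 36.7% in library 6 and the highest 43.6% in library 4. Leaving out Dam-only library 5 or Dam-LMNB1 library 6 turned the difference to 0.51 and 0.27. Shares of bins above the mean count of the cell were similar to the called ones, 39.4% in Dam-LMNB1 and 41.5% in Dam-only. As Dam-only is not tethered, these shares do not measure how much of the genome touched the lamina.

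Cells were more alike in the zygote library than at the 2-cell stage. The mean correlation of 1-Mb profiles between cells was 0.350 in the zygote library and 0.183 ± 0.020 in 2-cell Dam-LMNB1 (SD, n = 5 libraries, from 0.166 to 0.216). For Dam-only it was 0.143 ± 0.038 (n = 2; exact permutation p = 0.19 against Dam-LMNB1, 21 splits), for Dam-2E12 0.146 and for Dam-2E12mut 0.132. With 1 zygote library no test was made. Correlation at a fixed depth also depends on how uneven a profile is, and disjoint parts of equal size from 1 cell's counts correlated at 0.494 in zygotes and 0.252 ± 0.056 in 2-cell Dam-LMNB1. These parts hold 1500 counts, a depth at which different cells correlated at 0.253 in zygotes and 0.116 ± 0.019 in 2-cell Dam-LMNB1. The ratio of the correlation between cells to that between parts was 0.512 in the zygote library, inside the range of the 2-cell libraries (0.428 to 0.516, mean of the ratios 0.466). With the authors' contact calls in 100-kb bins and without thinning, the zygote exceeded the 2-cell libraries by 0.003.

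The sister cells of a 2-cell embryo had Dam-LMNB1 profiles more alike than those of cells from different embryos. Over 35 pairs of cells of 1 embryo in 5 libraries the mean correlation of Dam-LMNB1 profiles was 0.231 ± 0.050 (SD over pairs), against 0.175 over 719 pairs of cells of different embryos in the same library. The excess of 0.056 was positive in 5 of 5 libraries, from 0.041 in library 4 to 0.095 in library 5, and passed the permutation of embryo labels (p = 1e-05, the smallest that 100000 resamples give). Dam-only cells had an excess of 0.044 over 8 pairs (permutation p = 0.015). Dam-2E12 had 0.037 over 3 pairs (permutation p = 0.13) and Dam-2E12mut 0.079 over 2 pairs (permutation p = 0.14). The difference between Dam-LMNB1 and Dam-only was not tested.

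**Figure D4:**
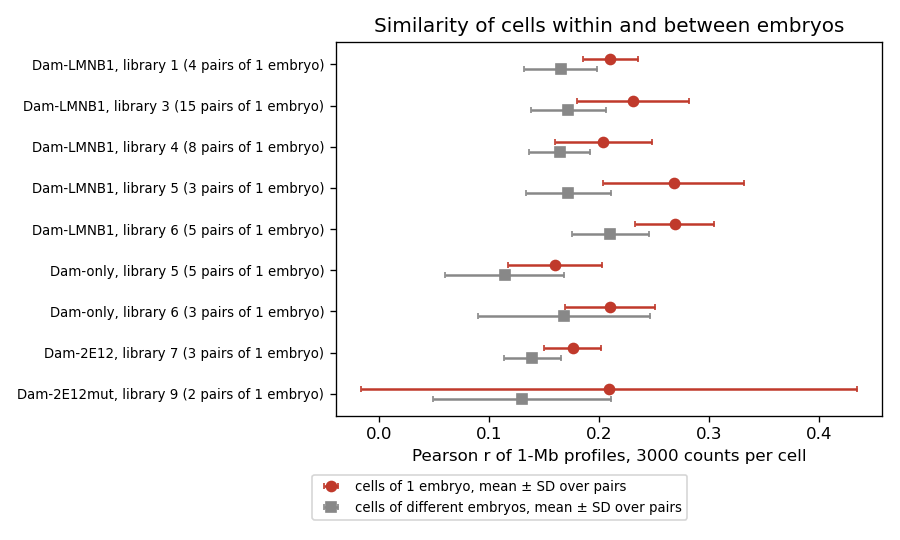
Pearson correlation of 1-Mb profiles at 3000 counts per cell, for pairs of cells of 1 embryo (circles) and of different embryos (squares), as mean ± SD over pairs in each library. Cells of 1 embryo lie above cells of different embryos in all 5 Dam-LMNB1 libraries, 0.231 against 0.172 in library 3.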

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

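Of the tests in this part, the 2 on the X chromosome and the control with library 7 were chosen after the result was seen; the tests on sister cells and on the zygote were written down before their values were known, although their patterns came from the same data.

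Sister cells of 2-cell embryos had Dam-LMNB1 profiles more alike than cells of different embryos, by 0.056 in correlation. If the number of X chromosomes were the source, the excess would vanish on autosomes, where it was 0.053. Spill-over between wells would raise pairs of different embryos with adjacent barcodes, since 31 of 36 sister pairs had such barcodes, but 18 such pairs of different embryos differed from the rest by -0.0014. A profile set in the zygote and passed to both daughters, or a shared dose of the injected construct, may account for it and stays untested. The excess in Dam-only cells, 0.044, leaves open whether it belongs to the lamina.

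In 1-Mb bins the zygote library differed from the 2-cell libraries in 1237 of 2628 bins, with gene-poor regions such as that of Lrrc4c higher and gene-dense ones such as that of Ctcf lower. The values argue against a low library total: each of the 6 2-cell libraries was thinned to the zygote total of 52017 counts and set against the others. Each gave 0 called bins (edgeR, 68 to 305 at an unadjusted p under 0.05 against 1438 for the zygote, and at most 22 called without thinning). Summed counts were thinned, so low depth per cell was not tested. Zygote cells had 3358 to 10179 counts, and 2-cell Dam-LMNB1 wells had at least 12080. A difference of library 8 was tested on its single Dam-2E12mut cell, which deviated from library 9 along the same bins as the zygotes from the 2-cell stage (rho = 0.395 over 1-Mb bins, shift p = 0.000381), but the Dam-2E12 cells of library 7 did so too (rho = 0.409), as a difference shared by libraries 7 and 8 or one of library 9 would give. Libraries 7 and 8 share a code in their titles that no 2-cell Dam-LMNB1 library carries, and all zygotes came from library 8, so stage cannot be told apart from library or code, and a sharper partition of the genome at the lamina in the zygote is only a candidate explanation.

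The X chromosome was lower in Dam-2E12 than in Dam-2E12mut, with X counts at a median 2.71% of autosomal counts in the 6 Dam-2E12 cells and 4.15% in the 14 cells of library 9. Embryo sex is part of it, as Y counts exceeded 0.05% of autosomal counts in all 6 cells and in 9 of the 14. It does not account for all: against those 9 cells alone the log2 ratio of medians was -0.435, and by embryo 2.76% ± 0.28 (SD, n = 3) stood against 3.75% ± 0.36 (n = 9), from 1 library each. The lone Dam-2E12mut cell of library 8, which shares a code in its title with the Dam-2E12 library, had 2.96%, inside the range of the Dam-2E12 cells (2.40% to 3.14%), so a pattern common to those libraries cannot be told apart from the mark with 1 cell, whose label may be wrong. A lower H3K27me3 level on the single X of male embryos may also be at work and was not tested.

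A sample stood far from the others in 1 further case: the spread of autosome shares between cells was 11.28 times the Poisson variance in Dam-LMNB1 library 6, against 5.54 to 7.05 in the other 4 libraries with enough cells. Chance alone marks about 1 in 20 groups in this way. A signal in data that no comparison of the design uses was the Y chromosome, which exceeded 0.05% of autosomal counts in both cells of 27 embryos and in neither cell of 22, with no embryo whose cells disagreed among 49. That limit was chosen after the values were seen, and at 0.1% the cells of 4 embryos disagreed. The authors' quality score had a median of 6.967 in the zygotes, which carry Dam-LMNB1. In the 2-cell Dam-LMNB1 arms the medians ran from 1.61 in library 4 to 3.506 in library 6. They were 1.486 and 1.461 in the 2 Dam-only arms.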

How the results depend on the processing

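Alternatives were listed before the data were examined, except 1-Mb bins in the count tests, the embryo as replicate (with library totals in place of TMM, so that 2 choices change together), single-cell wells alone, autosomes for sister cells, the ratio to disjoint parts of a cell, 10-kb bins for the stage lists and the fit without a block in 2 libraries, which were chosen after seeing the data. Where a result changed, the cause was not tested unless fewer or larger bins explain it. For Dam-LMNB1 against Dam-only the split into 6159 higher and 7353 lower bins was less stable than the total. It was 2787 higher and 9002 lower with DESeq2 size factors, and 2576 and 8589 with the DESeq2 Wald test. The total alone stayed within 1.5 times of 13512 in 20 of 24 alternatives, both of these included. The exceptions were fewer, larger bins (1511 at 1 Mb, 1710 at 1 Mb by embryo with library totals), 10-kb bins (48558) and leaving out libraries: the range was 7753 to 14331, the low values coming without Dam-only library 6 (7753) and library 5 (9259). With the library as a block in the 2 libraries that hold both constructs, 13642 bins were called, and 14249 without the block. These arms share a library number, not animals, their deviations correlated at 0.034 and -0.128, and 2 pairs decide nothing on pairing. The zygote count of 10 was the least stable: it was 41 with DESeq2 size factors, 169 with library totals, 425 with the Wald test, 0 with only the 2 groups, 27 with thinned cells, 0 with cells of at least 10000 counts, 16 on autosomes, 0 with single-cell wells, 0 at 10 kb, 334 by embryo with library totals, 1237 at 1 Mb (650 higher, 587 lower) and 1443 at 1 Mb by embryo with library totals (487 higher, 956 lower), all higher except at 1 Mb, with 1 to 21 when a library was left out (1 without library 1 or 3, 21 without library 4); the settings at 0 had 4174 to 5690 bins at an unadjusted p under 0.05 at 100 kb and 27480 at 10 kb. Dam-2E12 against Dam-2E12mut stayed at 0 in all 15 alternatives of edgeR and the Wald test, leave-one-out included (0 to 0; unadjusted counts 512 to 1664 at 100 kb), and Dam-2E12mut against Dam-only at 0 in 17 of 19, with 1 at 10 kb and 1 by embryo with library totals. The lamina and H3K27me3 correlation of 0.0005 became 0.0342 on autosomes, 0.09 at 1 Mb, -0.0824 with controls crossed and -0.0837 as a partial correlation, and ranged from -0.0156 to 0.0282 without 1 library. The difference of medians of -0.009 became 0.027 on autosomes, 0.077 at 1 Mb (permutation by shifts, p = 0.0019) and -0.074 as a partial value (p = 0.00086), and ranged from -0.049 to 0.038, with a call at -0.036 without library 9 (p = 0.0491). The difference in contact share of -0.48 percentage points was -2.1 with bins above the mean count of the cell and -1.85 on autosomes, and ranged from -1.47 to 0.51 without 1 library. The excess similarity of zygotes, 0.167, fell to 0.053 at 100 kb, 0.137 at 1500 counts, 0.003 with contact calls at 100 kb without thinning, which changes 3 choices at once, and 0.046 as a ratio to disjoint parts of a cell, and ranged from 0.153 to 0.188. Sister cells kept their call in all 8 alternatives. Their excess of 0.056 was 0.053 to 0.061 without 1 library and 0.053 on autosomes. It was 0.012 at 100 kb and 0.125 with contact calls at 100 kb without thinning. Library 2 had no pair of different embryos and did not enter. Camera called 0 lists for the lamina with the estimated correlation in 100-kb bins, 9 with the preset correlation and 7 with the estimated one in 10-kb bins. For the stage these were 2, 7 and 0.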

Other observations

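The correlations between cells of 1 construct at 1500 or 3000 counts or with contact calls, and the values without library 8, were planned, and the other tests in this part were chosen after the data were seen. The shares of whole chromosomes varied more between Dam-LMNB1 cells than between Dam-only cells. Whether this reflects lamina contact or technical variation between cells was not tested. At 3000 counts per cell the share of an autosome varied between Dam-LMNB1 cells by 7.41 ± 2.26 times the Poisson variance (median over 19 autosomes, SD over 5 libraries) and between Dam-only cells by 1.35 ± 0.29 (n = 2; exact permutation p = 0.0476, the smallest of 21 splits). Chromosomes 4 and 3 had the highest means, at 13.36 ± 4.70 and 13.25 ± 8.23 times, and the gene-dense chromosome 11 the lowest, at 4.03 ± 2.35. Chromosome 8 had 12.72 ± 9.78. At equal relative spread this measure is larger for a chromosome with a larger share, so the order is uncertain. The zygotes had 12.18, with 29.76 for chromosome 1, Dam-2E12 0.91 and Dam-2E12mut 2.07. At 1500 counts, and relative to disjoint parts of 1 cell's counts, Dam-only cells were more alike (ratio 0.684 ± 0.066, n = 2) than Dam-LMNB1 cells (0.466 ± 0.032, n = 5; exact permutation p = 0.0476), while the correlation itself was lower in Dam-only, at 0.078 against 0.116 (exact permutation p = 0.0952).

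X counts ranged widely between Dam-LMNB1 cells. In wells without Y (at most 0.05% of autosomal counts), X counts ran from 2.56% to 12.59% of autosomal counts over 51 Dam-LMNB1 wells and from 6.43% to 6.94% over 7 Dam-only wells, with coefficients of variation of 28.6% and 2.5% between single cells. In wells with Y these coefficients were 32.8% and 21.9%, a smaller contrast, and the medians were 4.46% over 46 Dam-LMNB1 wells and 3.56% over 21 Dam-only wells. The Dam-only wells with Y between 0.05% and 0.1% had X at 6.08%, 5.66% and 5.19% (Y at 0.0778%, 0.0839% and 0.0881%). At a limit of 0.1% they would count as without Y, so the Dam-only range and both Dam-only coefficients depend on the limit. Library 2 had 0 of 9 wells above the Y limit and library 1 had 3 of 13, while library 3 had 22 of 35. Zygotes had too few counts for this call.

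The single Dam-2E12mut cell of library 8 resembled Dam-2E12 cells. At 10000 counts its 1-Mb profile correlated with them at a mean of 0.345, inside the range of the Dam-2E12 cells with each other across embryos (0.330 to 0.351), while the 14 cells of library 9 had 0.155 to 0.308. With the cells of library 9 it had 0.248. A wrong label of this cell cannot be excluded. Without it the correlation of lamina and H3K27me3 ratios changed from 0.0005 to 0.0282 and the difference of medians from -0.009 to 0.038. Under the authors' contact calls without thinning, cells of library 9 correlated with each other at 0.020 and Dam-2E12 cells at 0.396, whereas at 3000 counts per cell these were 0.132 and 0.146.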
